A study of Zea mays with 4 samples.

How the data were processed

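The deposited values were FPKM (fragments scaled by transcript length and by the number of mapped fragments) per locus, 1 file for each of the 4 libraries: rea1 and wild-type endosperm at 15 days after pollination, total and polysome-bound RNA. Per the labels' protocols, total and polysome-bound RNA came from the same amount of powdered tissue, and the polysome-bound RNA was the pellet of a spin through a sucrose cushion. Per the submitters' processing notes, Bowtie 0.12.2 and the genome B73 RefGen_v3 were used. The program that computed FPKM, the annotation and the exact denominator are not given in the sources used here. The design text of the series speaks of triplicates, while each file holds 1 value per locus; whether and how replicates were combined is not given, so each file was treated as 1 library and no p-value was computed between the genotypes. An FPKM value is a share of its library, so a change in a few very abundant loci moves the values of all others, and an exact 0 can be a failed estimate; loci at 0 are described as listed at 0 and no fold is given against them.

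Each file listed 29642 loci by chromosome, start and end, with 28825 distinct coordinates; 1595 entries shared theirs with another entry. No entry carried a gene name. The gene table at hand was of another genome build, so no names were joined and no coordinates were converted, and the 29 gene lists fixed before the data were examined, the share of zein genes and any value for midasin were not used. Starts were read as counted from 0, since 48 of the 73 organelle loci had a length that was a multiple of 3 that way and 16 the other way, and are printed counted from 1.

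Ratios were taken on the log2(FPKM + 1) scale, which understates differences of low loci, for the 17682 loci with a mean over the 4 libraries of at least 1 FPKM, and loci at least 2-fold apart were counted. The change of the polysome-to-total ratio was the log2 ratio of rea1 over wild type in polysome-bound RNA minus that in total RNA. These choices, and the rule for named loci, were fixed before the data were examined. Where no names could be joined, the rule took at most 2 higher and 2 lower loci for each of the total, polysome and ratio-change comparisons, by log2 ratio among loci with a mean of at least 5 FPKM. Chosen after the data were examined were the abundance and length classes, the 70 abundant loci (mean of at least 1000 FPKM) and their grouping (gaps of up to 500 kb), the second ranking among loci above 0 in all libraries, the scan of positions in windows of 30 loci with 1000 shuffles, and all tests of explanations. In the abundance classes the class came from the RNA fraction that the ratio did not use. The median ratio of a group of loci was placed among 10000 random lists of the same size. These were drawn from the same bins of 100 loci by rank of mean FPKM, from which the group's own loci were not left out. All 70 abundant loci fell in the bin of the 100 most abundant loci, so their lists were drawn from that bin alone.

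Alternatives fixed beforehand were a pseudocount of 0.1 or 5, no filter on low values or a mean of at least 10 FPKM, and scaling by the median of ratios, by a trimmed mean (unweighted) or by the sum without the 50 most abundant loci. Added after the data were seen were a paired fit of polysome-bound against total RNA (limma 3.58.1 in R 4.3.3, trended eBayes on log2(FPKM + 1), genotype as a block, 1 residual degree of freedom), loci above 0 in all 4 libraries, loci that share no coordinate, and a gap of up to 1 Mb between grouped loci. Absolute depth was not given; relative depth within a genotype was read from the ratio of the lowest values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The counting and scaling steps were tested on simulated rea1 and wild-type total RNA values for 9769 loci: 100% of the loci set 4-fold higher and 100% of those set 4-fold lower were recovered, 0 unchanged loci were counted, and a simulated composition shift of 0.94 (log2) was removed by each of the scalings. That simulation held no replicate noise and so says nothing about error. All but the most abundant loci were given the same shift in it, so the removal of the shift checks the calculation only. The paired fit was tested on 17682 loci simulated with a noise of 0.3 (log2 SD): 100% of the loci set 4-fold apart were recovered and 10 unchanged loci were called. The loci set apart were not drawn from the least abundant, the noise was alike at all levels, and no genotype difference was simulated. These rates therefore do not carry over to the deposited values.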

Results

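RNA was measured in maize (Zea mays) endosperm, the starch- and protein-storing tissue of the kernel, at 15 days after pollination, in the rea1 mutant and in wild type. For each genotype there was a library of total RNA and a library of polysome-bound RNA, the RNA that pelleted with ribosomes through a sucrose cushion, which gave 4 libraries with 1 in each group. The labels do not state which gene is mutated in rea1. In yeast, Rea1 (midasin) is an AAA ATPase that acts in the maturation of the large ribosomal subunit. The values were FPKM per locus, given by position on B73 RefGen_v3 without gene names, so loci are named here by chromosome, start and end. With 1 library per genotype and RNA fraction, the genotype differences had no replicate check and no test; they are given by size, and higher or lower refers to these libraries.

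A small number of loci held most of the summed FPKM in wild type and much less of it in rea1 total RNA. The 10 most abundant loci of each library held 43.8% of the summed FPKM in wild-type total RNA, 38.5% in wild-type polysome-bound RNA, 27.97% in rea1 polysome-bound RNA and 13.4% in rea1 total RNA. The 50 most abundant held 64.4%, 60.7%, 45.8% and 25.4% in the same order. The median over 29642 loci was 2.85 FPKM in rea1 total RNA, against 1.69 in wild-type total RNA, 1.67 in rea1 polysome-bound RNA and 1.4998 in wild-type polysome-bound RNA. The summed FPKM of the libraries lay between 846544 and 977156. The number of loci above 0 was 26748 in rea1 total, 25826 in wild-type total, 25886 in rea1 polysome-bound and 25467 in wild-type polysome-bound RNA. Read totals were not given in the sources used here. The lowest values were most often 1.39 times as large in total as in polysome-bound RNA in rea1, and 1.23 times in wild type. Of the low loci, 36.3% and 36.4% lay within 0.1 (log2) of that step. A fragment adds more FPKM at a lower depth, so by this step polysome-bound RNA would have the greater depth in both genotypes. The exact denominator of FPKM is not given, however, and more loci were above 0 in total RNA of each genotype. The order of depth therefore stays uncertain. Between genotypes no clear step was found.

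**Figure D1:**
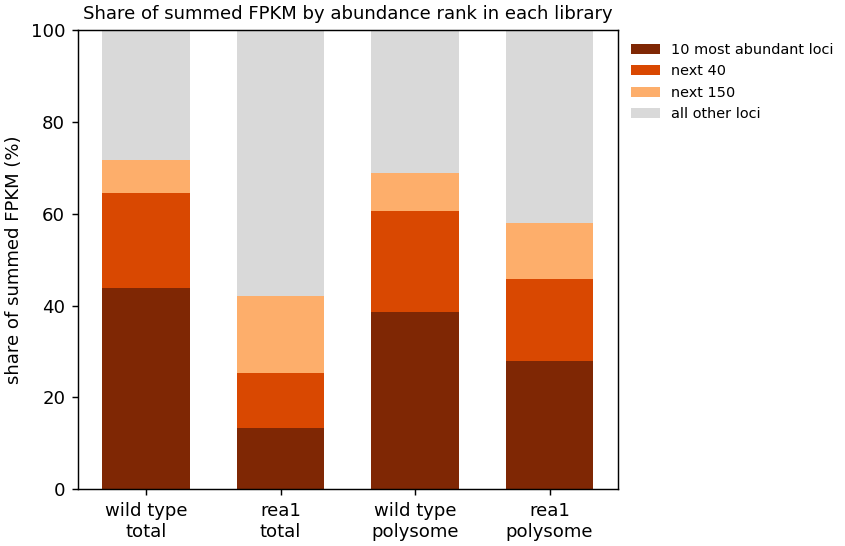
Share of the summed FPKM (percent, vertical axis) held by the 10 most abundant loci, by the loci next in rank up to the 50th and up to the 200th, and by all other loci, in each of the 4 libraries (bars). The 10 most abundant loci held 43.8% in wild-type total RNA and 13.4% in rea1 total RNA.

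The first comparison asks how total RNA differs between rea1 and wild-type endosperm. Groups of neighbouring, very abundant loci were lower in rea1. Among the 70 loci with a mean of at least 1000 FPKM, 26 lay within 500 kb of another and formed 6 groups, and 25 of these 26 were at least 2-fold lower in rea1 total RNA. The 13 loci at 5.08 to 5.56 Mb of chromosome 4 summed to 136311 FPKM in wild type and 24213 FPKM in rea1, a 5.63-fold difference, and all 13 were at least 2-fold lower. The 3 loci at 29.95 to 30.09 Mb of chromosome 4 were 6.44-fold lower in sum, the 4 at 18.76 to 18.88 Mb of chromosome 7 were 5.76-fold lower, the 2 at 161.79 to 162.01 Mb of chromosome 1 were 5.37-fold lower and the 2 at 39.09 Mb of chromosome 6 were 7.24-fold lower. In the group at 120.21 to 120.24 Mb of chromosome 7, 1 locus was lower (1621 FPKM in rea1, 9911 in wild type), while the other (120233940 to 120236057) was listed at 0 in wild-type total RNA and at 31354 FPKM in rea1. All 26 grouped loci together were 4.09-fold lower in rea1, and the 24 that were above 0 in all 4 libraries were 5.70-fold lower. The log2 ratio of the sum of all 26 was -2.03 as deposited and between -2.95 and -2.77 under the other scalings.

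The other abundant loci went both ways. Of the 44 loci with a mean of at least 1000 FPKM outside the groups, 9 were at least 2-fold lower and 9 at least 2-fold higher in rea1 total RNA. These counts are as deposited, and so is their sum, which was 1.61-fold lower in rea1. Without the 3 most abundant of them the sum of wild type over that of rea1 was 0.844, so it was then higher in rea1 as deposited. With median-of-ratios scaling the factor was 1.45 for rea1 total RNA and 0.86 for wild-type total RNA, which turns that direction. The other 2 scalings do so too. The median log2 ratio of the 44 loci was 0.36 as deposited and -0.26 relative to the median of all tested loci. Of the 44, 36.4% were at or above that median, so the sign of their median ratio depended on the scaling. The median log2 ratio of the 13 loci of the chromosome 4 group at 5.08 to 5.56 Mb was -2.68. It lay at percentile 0.0 of 10000 random lists drawn from the 100 most abundant loci. The groups at 29.95 Mb of chromosome 4 and 18.76 Mb of chromosome 7 lay at percentiles 2.94 and 1.33, and the 44 loci outside the groups at 57.3. Such lists match abundance only coarsely. The 44 loci make up much of the 100 drawn from, which pulls their own percentile towards the middle. The random lists were drawn as if loci were independent, which neighbours that share reads are not, so a percentile only places a median. The groups and the limit of 1000 FPKM were chosen after the values were seen. Storage-protein gene families have near-identical copies in maize, and the value of any single locus of a group is uncertain where copies share reads.

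Across all 17682 loci with a mean of at least 1 FPKM, 4647 were at least 2-fold higher and 338 at least 2-fold lower in rea1 total RNA on the log2(FPKM + 1) scale, with a median log2 ratio of 0.62. FPKM is relative to the whole library, and this split depended on the scaling: with median-of-ratios scaling, which sets the median ratio near 0 (-0.01), 1171 loci were higher and 1023 lower. Rescaled to equal sums without the 50 most abundant loci, 897 were higher and 1426 lower. The median shift was similar on every chromosome, from 0.59 to 0.64. By abundance in polysome-bound RNA, the median log2 ratio in total RNA was 0.55 for 9657 loci at 1 to 10 FPKM, 0.70 for 5920 loci at 10 to 100, 1.102 for 733 loci at 100 to 1000 and -0.97 for 67 loci at 1000 or more. The largest differences that the rule for named loci took included chromosome 8, 132250530 to 132252119, at 3.54 FPKM in rea1 and 219 in wild type (log2 ratio -5.60), and chromosome 1, 162047479 to 162097052, at 9.63 and 415 FPKM (-5.29). This chromosome 1 locus, 49574 bp long, lies beside the group at 161.79 to 162.01 Mb, and whether it shares reads with that group was not examined. The higher loci under the rule were both listed at 0 in wild-type total RNA: the chromosome 7 locus above and chromosome 2, 198478457 to 198479148, at 284 FPKM in rea1. Among loci above 0 in all 4 libraries, a ranking added after the data were seen, chromosome 3, 201981099 to 201981984, had the highest ratio on the log2(FPKM + 1) scale, with 1253 FPKM in rea1 and 3.69 in wild type. Without the pseudocount, chromosome 4, 124589273 to 124591934, was further apart, at 79.0 and 0.180 FPKM.

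**Figure D2:**
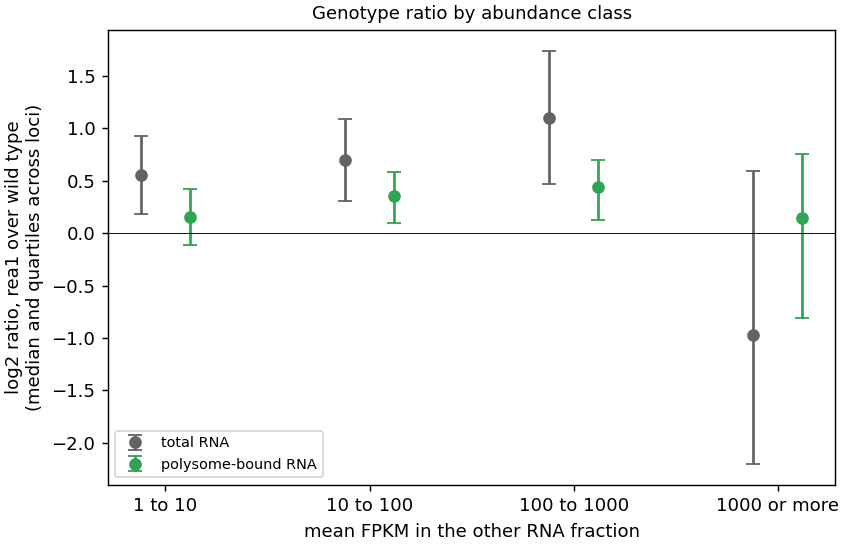
Log2 ratio of rea1 over wild type (vertical axis; points, medians over loci; bars, quartiles) in total and polysome-bound RNA, by the mean FPKM of the loci in the other RNA fraction (horizontal axis). In total RNA the median was 1.102 at 100 to 1000 FPKM and -0.97 at 1000 FPKM or more.

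The second comparison asks how the RNA on polysomes differs between the genotypes. All 6 groups of abundant loci were lower in sum in rea1, and the 5 that were lower in total RNA were so by smaller folds here; the group at 120.21 to 120.24 Mb of chromosome 7 was higher in sum in rea1 total RNA, where 1 of its loci was listed at 0 in wild type. The chromosome 4 group at 5.08 to 5.56 Mb summed to 165742 FPKM in wild type and 82532 in rea1, a 2.01-fold difference, with all 13 loci lower and 6 at least 2-fold lower. The sums were 2.06-fold lower for the group at 29.95 to 30.09 Mb of chromosome 4, 2.38-fold lower for chromosome 1, 2.59-fold lower for chromosome 6, 1.43-fold lower for chromosome 7 at 18.76 to 18.88 Mb and 1.37-fold lower for chromosome 7 at 120.21 to 120.24 Mb. Together the 26 loci were 1.84-fold lower, and 25 of them were below a ratio of 1. The exception, chromosome 7, 18865424 to 18866146, was listed at 0 in both polysome libraries. Of the 44 abundant loci outside the groups, 3 were at least 2-fold lower and 7 at least 2-fold higher, with a median log2 ratio of 0.50.

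Over all tested loci, 701 were at least 2-fold higher and 237 at least 2-fold lower in rea1 polysome-bound RNA, with a median log2 ratio of 0.24. With median-of-ratios scaling the split was 337 higher and 471 lower, and without the 50 most abundant loci it was 287 higher and 542 lower. The locus on chromosome 3, 201981099 to 201981984, was at 307 FPKM in rea1 and 2.84 in wild type (log2 ratio 6.33), and the locus on chromosome 2, 198478457 to 198479148, at 98.5 FPKM in rea1, was listed at 0 in wild type. The lower entries under the rule were both listed at 0 in rea1 polysome-bound RNA and share their coordinates with another entry. They were chromosome 1, 246090026 to 246092492, at 315 FPKM in wild type, and chromosome 3, 204651106 to 204656000, at 34.6 FPKM. The other entry at the chromosome 1 coordinates was above 0 in all 4 libraries and went the other way, with a log2 ratio of 1.01. That locus therefore cannot be called lower in rea1. The locus on chromosome 8, 132250530 to 132252119, which was low in rea1 total RNA, was at 20.7 FPKM in rea1 polysome-bound RNA and 190 in wild type.

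The genotype differences of both RNA fractions overlapped. Of the tested loci, 434 were at least 2-fold higher in rea1 in both fractions, where independent lists of those sizes would share 184.2, and 84 were at least 2-fold lower in both, where independent lists would share 4.5. In 22 loci the directions were opposite. With median-of-ratios scaling, 116 were higher in both (22.3 for independent lists) and 195 were lower in both (27.2). Across loci, which are not independent replicates, the log2 ratios of the fractions had a Pearson r of 0.428 and a Spearman rho of 0.398. These comparisons share no library, but the labels' protocols do not rule out that both RNA fractions of a genotype came from one tissue sample, in which case a difference between samples would enter both.

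**Figure D3:**
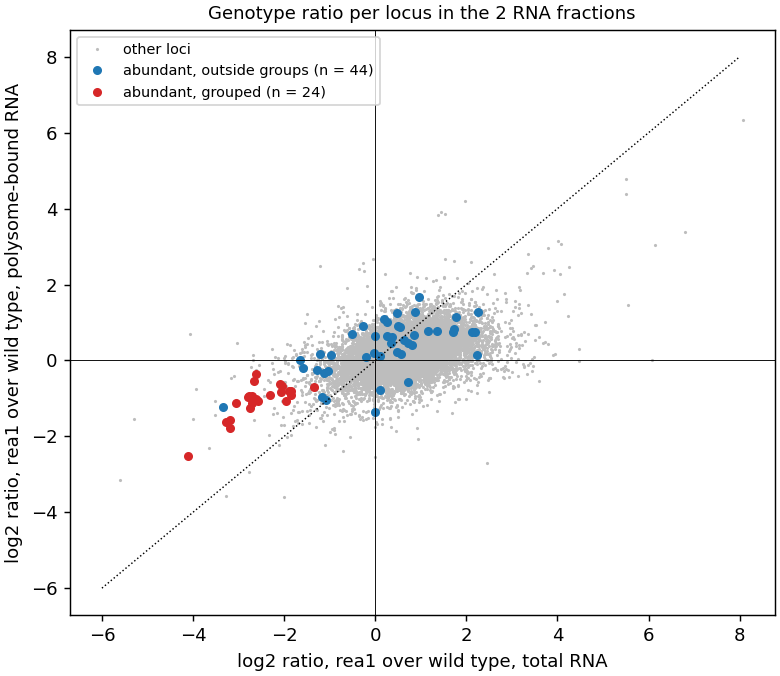
Log2 ratio of rea1 over wild type per locus in total RNA (horizontal axis) and polysome-bound RNA (vertical axis), for loci with a mean of at least 1 FPKM that were above 0 in all 4 libraries; the dotted line marks equal ratios. The 24 grouped abundant loci (red) lie below 0 in both fractions and left of the line of equal ratios, and the 44 abundant loci outside the groups (blue) spread to both sides of 0 as deposited.

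The third comparison sets polysome-bound against total RNA within each genotype. Because FPKM is relative to each library, this ratio does not measure the share of a transcript that is on polysomes. In wild type, the chromosome 4 group at 5.08 to 5.56 Mb had a polysome-to-total ratio of 1.22 in sum, and in rea1 it had 3.41. Its loci differed widely in wild type, with log2 ratios from -0.711 to 4.247. The median over its loci was 0.065 (log2) in wild type and 1.733 in rea1. The chromosome 4 group at 29.95 to 30.09 Mb had ratios of 1.13 in wild type and 3.53 in rea1. The chromosome 7 group at 18.76 to 18.88 Mb had a ratio of 0.182 in wild type, the lowest of the 6 groups, and 0.736 in rea1. Without its locus listed at 0 in both polysome libraries these were 0.341, still the lowest in wild type, and 1.29, above the 1.11 of the chromosome 7 group at 120.21 to 120.24 Mb in rea1. Mitochondrial loci, 51 in number, summed to less in polysome-bound than in total RNA, with a ratio of 0.264 in wild type and 0.401 in rea1. The 22 plastid loci, whose sums were below 2 FPKM in each library, had a ratio of 0.527 in wild type and 1.20 in rea1.

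In wild type 797 loci were at least 2-fold higher and 1232 at least 2-fold lower in polysome-bound RNA, with a median log2 ratio of -0.06. In rea1 515 were higher and 3582 lower, with a median of -0.47, and with median-of-ratios scaling 1191 were higher and 1437 lower. In both genotypes 250 loci were higher (23.2 for independent lists) and 874 lower (249.6). A limma fit over the 4 libraries with genotype as a block, added after the data were seen, called 333 loci higher and 1309 lower in polysome-bound RNA at an adjusted p under 0.05 (Benjamini-Hochberg), and 487 higher and 689 lower with median-of-ratios scaling. It had 1 residual degree of freedom, borrowed its spread across loci, and counted any genotype difference in the ratio as error. Short loci were more often at least 2-fold lower: 27.8% of the 388 loci under 600 bp in wild type and 44.9% in rea1, against 4.86% and 17.2% of the 6995 loci of 4800 bp or more. Short loci were also more often at least 2-fold higher, 11.9% in wild type and 9.54% in rea1 against 2.20% and 1.54%. The length is that of the locus, introns included.

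**Figure D4:**
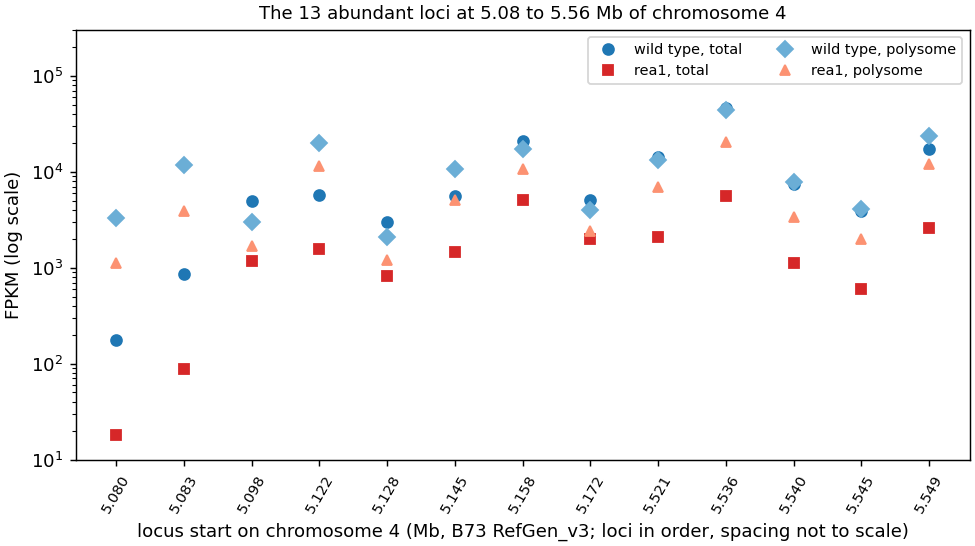
FPKM (vertical axis, log scale) of the 13 abundant loci at 5.08 to 5.56 Mb of chromosome 4 in the 4 libraries (points), in order of position on B73 RefGen_v3 with spacing not to scale. Each locus was lower in rea1 than in wild type in both RNA fractions, 5.63-fold in sum in total RNA and 2.01-fold in polysome-bound RNA.

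The last comparison is the change of the polysome-to-total ratio in rea1 against wild type. Of the tested loci, 363 had a ratio at least 2-fold higher in rea1 and 2745 at least 2-fold lower, with a median of -0.37 (log2). With median-of-ratios scaling 838 were higher and 1179 lower, and without the 50 most abundant loci 1052 were higher and 987 lower. On chromosome 7, the locus at 18867732 to 18868453 was at 983 FPKM in wild-type total RNA and 58.0 in wild-type polysome-bound RNA, and at 57.5 and 95.3 in rea1, a change of 4.78 (log2). It lies within the span of the abundant group at 18.76 to 18.88 Mb, close to the locus at 18865424 that was listed at 0 in both polysome libraries. Whether it shares reads with that group was not examined. The locus at 119194704 to 119194893 of chromosome 3, also named by the rule, was at 28.4 FPKM in wild-type total RNA and listed at 0 in the other libraries. The lower loci under the rule rest on values listed at 0. Chromosome 7, 120233940 to 120236057, was at 34692 FPKM in wild-type polysome-bound and 28979 in rea1 polysome-bound RNA. The other was an entry at chromosome 1, 246090026 to 246092492, above 0 in wild-type polysome-bound RNA alone. A second entry at those coordinates was above 0 in all 4 libraries. Its log2 ratios of rea1 over wild type were 0.73 in total and 1.01 in polysome-bound RNA.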

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

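All tests of explanations in this part, with their limits, were chosen after the results were seen, and several were revised after a first outcome, as stated where it applies. The differences in direction listed here were not tested, since each rests on 1 library per group. The locus on chromosome 3, 204651106 to 204656000, was higher in rea1 total RNA (26.3 against 11.9 FPKM, log2 ratio 1.09) and was listed at 0 in rea1 polysome-bound RNA, against 34.6 FPKM in wild type. Its polysome-to-total ratio was 1.47 (log2) in wild type, and no fold is given in rea1; it shares its coordinates with another entry. In all, 16 loci were at least 2-fold higher in rea1 total RNA and at least 2-fold lower in rea1 polysome-bound RNA, and 6 went the other way. Against total RNA, 70 loci were at least 2-fold higher in polysome-bound RNA of wild type and at least 2-fold lower in that of rea1, and 10 went the other way.

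Most loci that differed in total RNA were higher in rea1, with a median log2 ratio of 0.62. After equal sums of all but the 50 most abundant loci the median was -0.15, but such a rescaling centres the remaining loci whatever moved them, so it does not decide whether scaling by a few very abundant loci is the cause. FPKM alone cannot say whether other transcripts were more abundant per cell, and a biological difference between the genotypes was not tested.

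The grouped abundant loci were lower in rea1 in both RNA fractions. Reads divided differently among the grouped copies, if of like length, would leave their sum alike. The sum of all 26 was 4.09-fold lower in total RNA (5.70-fold for the 24 above 0 in all libraries). Reads passed to copies outside the groups, or between loci of unlike length, could change a sum of FPKM, so these stay open. A fault of the rea1 total library alone would leave the polysome libraries alike, and there the sum was 1.84-fold lower, with 25 of 26 loci lower. A first reading of this comparison left the question open for the whole pattern. The pattern was then divided into the part found in both fractions and the excess in total RNA. The part found in both is thus defined by these polysome values, so the comparison is no test of that fault. The values show only that the grouped loci were lower in the rea1 polysome library too. One chromosome segment that differs between the plants and acts on the loci within it would hold them on 1 chromosome, and the 24 loci lower in both fractions lay on 4. The positions of the groups were already known, so this outcome was fixed beforehand. Reads shared between copies on different chromosomes were not examined either, so the count of chromosomes does not decide this. Differences at several sites were not tested and stay open. Genotype, the sample harvested and the library are the same split of these libraries, so a difference caused by the mutation stays open as a hypothesis.

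The 24 grouped loci above 0 in all libraries were lower in sum by 2.90-fold more in total than in polysome-bound RNA, and the sum of all 26 by 2.21-fold more, although the locus at 120233940 of chromosome 7, listed at 0 in wild-type total RNA, went the other way. The first test was of the 44 abundant loci outside the groups, whose median ratio in total RNA lay at -0.26 (log2) relative to all loci, with quartiles of -0.95 and 0.24 and 36.4% at or above it, against -3.25 for the groups; it leaves saturation at the most abundant loci open. After that outcome a second test was added, with the class median already known. Of 733 loci at 100 to 1000 FPKM, 68.3% lay above the median ratio of all loci. The exact binomial 95% interval, over loci, was 64.8% to 71.7%. The class median was 1.102 (log2) against 0.62 for all loci, so a majority above was fixed beforehand. The second test therefore cannot decide on a compressed range. The values show only that most loci at those levels were not lowered relative to all loci. They say nothing of the levels above. As deposited, the excess was 1.67-fold over the 44 abundant loci outside the groups, but 1.14-fold without the 3 most abundant of them. This test replaced another on the grouped loci alone. Both values depend on the scaling. The median-of-ratios factors were 1.45 for rea1 and 0.86 for wild-type total RNA, and 0.9955 and 0.807 for polysome-bound RNA. Dividing by them raises the excess at the remaining loci too, and so does each of the other scalings. Whether the excess rests on those 3 loci is therefore not decided. A fault of the rea1 total library stays open for the abundant loci. A difference between the genotypes in how these transcripts are held on ribosomes cannot be told apart from these with 1 library per group.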

How the results depend on the processing

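Counts are given as higher and lower, for rea1 against wild type in total RNA, then polysome-bound RNA, polysome-bound against total RNA in wild type, then in rea1, and the ratio change. Alternatives were fixed before the data were examined, except those named as added. Of the counts and correlations set against their main values, 58 stayed within 1.5-fold (0.1 for a correlation) and 50 did not. The excess of higher over lower loci turned in polysome-bound RNA (701 and 237 as deposited) under each of the 3 scalings, and in total RNA (4647 and 338) and the ratio change (363 and 2745) without the 50 most abundant loci. With median-of-ratios scaling the counts were 1171 and 1023, 337 and 471, 1002 and 1163, 1191 and 1437, and 838 and 1179. With trimmed-mean scaling they were 1204 and 1004, 343 and 451, 984 and 1187, 1164 and 1472, and 837 and 1184. Without the 50 most abundant loci in the scaling they were 897 and 1426, 287 and 542, 837 and 1441, 1125 and 1461, and 1052 and 987. With a pseudocount of 5 they were 2293 and 161, 248 and 90, 265 and 330, 213 and 1464, and 159 and 1209. With a mean of at least 10 FPKM, which tests fewer loci, they were 2419 and 152, 387 and 101, 324 and 365, 224 and 1233, and 165 and 1167. With a pseudocount of 0.1, 510 loci were lower in total RNA, 1385 higher and 508 lower in polysome-bound RNA, 1298 higher and 2095 lower in polysome-bound against total RNA of wild type, and 627 higher in the ratio change. Median-of-ratios and trimmed-mean scaling bring the median near 0 by construction; without the 50 most abundant loci it was -0.15 in total RNA and 0.10 in the ratio change. For the other settings the cause was not tested. No count moved by over 1.5-fold without a filter, or with the added settings of loci above 0 in all 4 libraries and of loci that share no coordinate. Pearson's r lay between 0.394 and 0.489. The summed grouped abundant loci were lower in rea1 under each scaling, with log2 ratios from -2.95 to -2.03 in total and from -1.26 to -0.88 in polysome-bound RNA, and with the added gap of up to 1 Mb, which takes in 27 loci, they were at -2.001 and -0.85.

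Alternatives not run were the gene lists and the removal of zein genes, for lack of gene names. The genotypes could not be compared with samples paired by replicate, because the labels give no replicate numbers that pair samples. A genotype fit with the RNA fraction as a block was left out, since both fractions may come from one sample and would then not be replicates; for the RNA fractions, the added fit with genotype as a block gave 333 higher and 1309 lower loci, and 487 and 689 with median-of-ratios scaling. Depth limits the low loci most, and its absolute size is unknown.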

Other observations

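All values in this part were picked after the data were seen. Outside the groups, the locus on chromosome 4 at 21334901 to 21335970 was at 52408 FPKM in wild-type total RNA and 5166 in rea1 total RNA, and at 43299 and 18398 FPKM in polysome-bound RNA. The locus on chromosome 2 at 183991961 to 183993036 was at 41136 FPKM in wild-type and 12994 in rea1 total RNA, and at 43734 and 44214 FPKM in polysome-bound RNA. Higher in rea1 in both fractions were chromosome 7, 157638031 to 157641018, at 1135 FPKM in rea1 and 23.8 in wild-type total RNA and at 549.9 and 19.1 in polysome-bound RNA, and chromosome 9, 22112240 to 22116928, at 2190 and 460.0 in total and 1383 and 572 in polysome-bound RNA.

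In 14 loci a library was listed at 0 while another held at least 50 FPKM. The most abundant, chromosome 7, 18865424 to 18866146, was at 91299 FPKM in wild-type and 14590 FPKM in rea1 total RNA and at 0 in both polysome libraries, while its neighbour at 18877460 to 18878182 was at 28102 FPKM in wild-type and 19471 in rea1 polysome-bound RNA. Plastid loci, 22 in number, summed to 1.63 FPKM in rea1 and 0.1502 in wild-type total RNA, and to 1.96 and 0.0791 in polysome-bound RNA.

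Outside the groups and 500 kb around them, the fullest window of 30 loci, on chromosome 6 at 138751831 to 140883690, held 4 loci lower in both fractions with median-of-ratios scaling, and 32.9% of 1000 shuffles of positions had a window as full. This scan leaves out the grouped loci and says nothing of them.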
